A study of Rattus norvegicus with 9 samples.

How the data were processed

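Poly(A) RNA from the femora of Sprague-Dawley rats was sequenced in 9 libraries, 3 each from normal (control), ovariectomized and Cistanche-treated rats, as the labels give them. Whole-number count values and FPKM values per gene were deposited, per the file headers, in 1 table of 32623 rows with Ensembl rat gene identifiers, symbols and coordinates. Per the submitters' processing notes the authors used fastp, HISAT2 and StringTie, with no versions; the genome build is not given in the sources used here. Where the deposited count is 0, the deposited FPKM is 0.0001, and this fill value was kept. The FPKM values had been scaled by the authors for gene length and depth. How the count values were made is not stated in the sources used here, and they were treated as unscaled read counts. Libraries held 54992823 to 66531156 counts. For read counts, sampling alone gives a gene with 100 counts an SD of about 10%, and the spread between libraries exceeded that of sampling in every pair.

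Genes with a mean of at least 1 FPKM over the 9 libraries were tested, 13886 in all. The design had named limma on log2(FPKM + 1) for a file without counts and provided for edgeR where counts were present, so edgeR was used for genes: TMM factors, 1 quasi-likelihood fit over all 9 libraries, and contrasts for ovariectomized against control, treated against ovariectomized and treated against control rats. Adjusted p values (Benjamini-Hochberg, threshold 0.05) came from edgeR unless another tool is named. The common biological coefficient of variation was 0.262, with 2.37 prior degrees of freedom. Fold changes carry the standard error of edgeR, and CPM values are means with SD over 3 libraries. An unadjusted p under 0.05 with at least a 2-fold change was counted as a looser threshold. With 3 libraries against 3, 10% of genes have groups that do not overlap by chance, and the smallest 2-sided exact permutation p is 0.1.

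Lists of 33 cell types and pathways with 738 distinct symbols were fixed before the data were examined; 33 of these symbols without a row under that name were not analysed here, and 648 passed the filter. Lists with at least 5 measured members were tested with limma's camera on log2(FPKM + 1), at the preset correlation of 0.01, and again with a correlation estimated per list and with fry. The 3303 ontology and pathway terms with 10 to 300 measured members came from the annotation columns of the same table and were tested in the same way. Medians of lists and terms in the results are medians of edgeR log2 fold changes, except that medians with a library left out or a covariate added are differences of log2(FPKM + 1). Members counted as adjusted over the list alone had their edgeR p values adjusted within that list.

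Genes were named by a rule fixed before the data were examined. For ovariectomized against control and treated against ovariectomized rats it took the 8 higher and 8 lower genes with the largest change among those past the threshold whose groups did not overlap (5 and 5 for treated against control rats), leaving out placeholder symbols. Open places went to non-overlapping genes of at least 2-fold with the smallest unadjusted p. It added up to 4 members of each described list with the smallest p, and always Tnfsf11, Tnfrsf11b, Acp5, Ctsk, Bglap, Runx2, Col1a1 and Esr1. Where rows shared a symbol (1556 symbols) the row with the highest mean FPKM stood for it. Some genes that the rule names are not reported here.

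The comparisons, thresholds, lists, naming rule and main alternatives were chosen before the data were examined. Those alternatives were another pseudocount, no filter or a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, only the 2 groups compared, a robust variance model, library weights, the replicate number as a block, and each library left out in turn. For genes, another pseudocount, TPM, quantile normalization and library weights were fitted with limma, and the others of these with edgeR. Limma and DESeq2 for genes, camera on edgeR log2 CPM, and the skeletal muscle score or the erythroid score as a covariate were added after seeing the data. The correlation of the ovariectomy and treatment differences was set against 1000 random draws (seed 1) of unchanged groups sharing the ovariectomized libraries. The edgeR step was tested on simulated data for 13886 genes with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 54% and 88% of them for ovariectomized against control rats, 48% and 80% for treated against ovariectomized rats and 46% and 83% for treated against control rats, with 5, 6 and 6 false calls. The simulated genes varied independently of each other at the fitted dispersions, without structure between libraries. The percentages thus check the step and do not give its power in the real libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. The labels do not state whether libraries are separate animals, and the p values measure the spread between these samples.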

Results

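Femoral gene expression was profiled by poly(A) RNA sequencing in Sprague-Dawley rats, with 9 libraries in 3 groups of 3. The groups were normal rats (control), rats whose ovaries had been removed (ovariectomized) and rats given the herb Desertliving Cistanche, a desert plant used in traditional Chinese medicine (treated). The series title places the treatment in ovariectomized rats as a model of postmenopausal osteoporosis; dose and duration are not given in the sources used here. Removal of the ovaries withdraws oestrogen, which in rats is followed by bone loss. The libraries held 54992823 to 66531156 counts each, over 32623 gene rows, of which 13886 had a mean of at least 1 FPKM and were tested. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples.

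A femur sample holds bone, marrow, cartilage and whatever soft tissue remains attached, and genes of blood and muscle differed in level between libraries within groups as well as between groups. Haemoglobin genes took 12.5% ± 3.23 of all counts in controls (SD, n = 3), 9.02% ± 0.929 in ovariectomized rats and 7.61% ± 1.05 in treated rats. The 2-sided exact permutation p was 0.1 for each of the latter groups against controls, the smallest value that 3 libraries against 3 allow, and 0.3 for treated against ovariectomized rats. Control replicate 2 had the highest share, 16.2%, and was also unlike the others for Hba-a3, an alpha-globin gene with near-identical copies, with 1575 counts against 21020 to 57619 elsewhere. The score of the skeletal muscle list (mean log2 CPM of its members relative to the 9 libraries) was -2.17 in control replicate 1 and 2.11 in ovariectomized replicate 3. Spearman correlations across genes ran from 0.970 to 0.983 within groups and from 0.965 to 0.982 between groups. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 80.02.

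**Figure D1:**
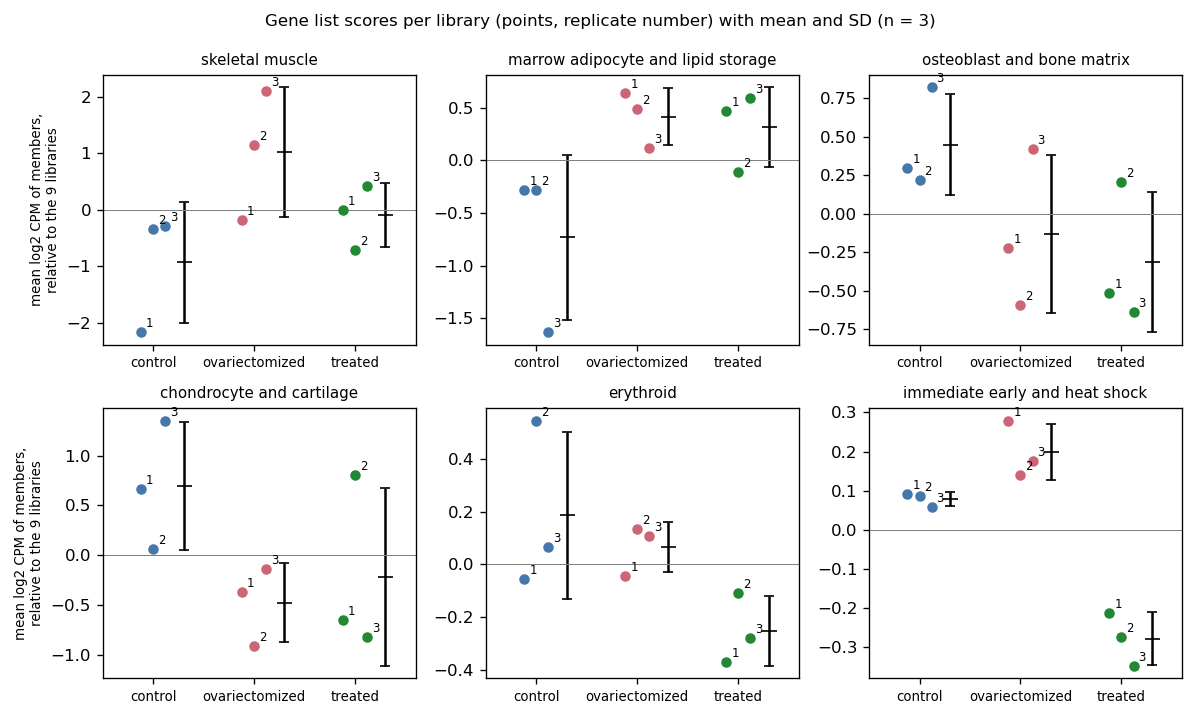
Scores of 6 gene lists in each library, as the mean log2 CPM of the members relative to the mean of the 9 libraries (vertical axes), for control, ovariectomized and treated rats; points are libraries with their replicate number, and the bar beside them is the mean with its SD (n = 3). The immediate early and heat shock score lay between -0.35 and -0.21 in the 3 treated libraries and above 0 in the other 6, whereas the skeletal muscle score spread from -2.17 to -0.28 among controls alone.

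The comparison of ovariectomized with control rats asks what loss of the ovaries does to the transcriptome of the femur. Genes of fat cells and lipid storage were higher: all 19 measured members of the adipocyte list had higher estimates, with a median log2 fold change of 1.09. Lpl, the lipase that releases fatty acids from circulating lipoproteins (chromosome 16, 22537056 to 22561496), had 110 ± 38.7 CPM in controls and 318 ± 74.9 CPM in ovariectomized rats (SD, n = 3), a log2 fold change of 1.53 ± 0.34 (SE). Retn, which encodes resistin, was at 1.43 ± 0.32, the lipid droplet gene Plin4 at 1.33 ± 0.38 and Pparg, the regulator of fat cell differentiation, at 0.69 ± 0.20. Of the 19 members, 8 passed at an adjusted p under 0.05 when adjusted over the list alone and 0 in edgeR when adjusted over all genes tested, where DESeq2 passed 2 (Lpl and Retn). Camera placed the list above other genes with an adjusted p of 1.77e-15 at its preset correlation, but with adjusted p = 0.745 with an estimated correlation. Control replicate 3 stood apart, with a list score of -1.63 against -0.28 in both other controls, and without it the median difference in log2(FPKM + 1) went from 1.14 to 0.70.

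Bone-forming and cartilage genes lay on the lower side. All 17 measured genes of the osteoblast and bone matrix list had lower estimates (median log2 fold change -0.42), among them Alpl, the alkaline phosphatase of mineralizing cells, at -0.35 ± 0.15 (SE), and Pth1r at -0.81 ± 0.36. The list passed camera (adjusted p = 1.34e-08; adjusted p = 0.745 with an estimated correlation), while 0 of its members passed in edgeR or DESeq2 over all genes tested, and 0 in edgeR when adjusted over the list alone. Of 16 cartilage genes, 14 were lower, with a median of -1.20. The cartilage collagens Col9a3 (-1.96 ± 0.60) and Col9a2 (-1.49 ± 0.48), the matrix link protein Hapln1 (-1.85 ± 0.64) and Cnmd (-2.28 ± 0.79) showed no overlap between the groups. Here the camera adjusted p was 5.38e-10, and adjusted p = 0.745 with an estimated correlation; 0 members passed in edgeR when adjusted over the list alone, and 0 over all genes tested in edgeR or DESeq2. In log2(FPKM + 1), the osteoblast median of -0.40 was -0.25 without control replicate 3 and -0.77 without ovariectomized replicate 3, and the cartilage median of -0.93 was -0.55 without control replicate 3.

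Skeletal muscle transcripts differed most. All 18 muscle genes were higher in ovariectomized rats, with a median log2 fold change of 1.85, and 16 of them passed when adjusted over the list alone against 0 in edgeR and 3 in DESeq2 (Eno3, Tnnc2 and Actn3) over all genes tested. The fast myosin heavy chain Myh4 was at 1.98 ± 0.51 (SE), and Actn3, Eno3 and the creatine kinase Ckm were at 1.54 ± 0.42, 1.74 ± 0.48 and 1.86 ± 0.55. Per library, the sarcomeric actin Acta1, chosen after its values were seen, ranged from 79.7 to 321 CPM in controls and from 355 to 2246 CPM in ovariectomized rats. Nuclear genes of oxidative phosphorylation (34 of 35 higher, median 0.11) and genes encoded in mitochondrial DNA (13 of 13 higher, median 0.23) moved with them by small amounts, including Mt-nd3 at 0.44 ± 0.12. The camera adjusted p values were 1.77e-15, 4.26e-09 and 2.40e-05 for muscle, oxidative phosphorylation and mitochondrial DNA. With an estimated correlation they were adjusted p = 0.745, adjusted p = 0.764 and adjusted p = 0.809. Without ovariectomized replicate 3 the median differences in log2(FPKM + 1) went from 0.15 to 0.09 for oxidative phosphorylation and from 0.27 to 0.16 for mitochondrial DNA, and Ckm was at 1.20.

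Interferon response genes were higher on average, 28 of 29, but this rested on ovariectomized replicate 1. Mx1, an antiviral GTPase, was at 183 CPM in that library and at 17.4 to 28.8 CPM in the other 8. The list passed camera (adjusted p = 0.00760; adjusted p = 0.809 with an estimated correlation), and without that library its direction turned, with a median of -0.11 and an adjusted p of 0.000553; without control replicate 3 it did not pass (adjusted p = 0.233). A further 6 lists passed on the lower side, each with adjusted p = 0.809 with an estimated correlation: megakaryocyte and platelet (17 of 19 lower), erythroid (20 of 21), marrow stroma (10 of 12), BMP and TGF-beta signalling (18 of 24), cell cycle (26 of 29) and osteocyte (9 of 10). Each of the 6 lost its call when single libraries were left out. The megakaryocyte list had adjusted p values of 0.169 without control replicate 2 and 0.0557 without ovariectomized replicate 3. The erythroid list had 0.165, with its direction turned, without control replicate 2 and 0.263 without ovariectomized replicate 1. Cell cycle genes had 0.0918, also turned, without control replicate 2, 0.0918 without control replicate 3, 0.446 without ovariectomized replicate 1 and 0.0738 without ovariectomized replicate 3. Stroma had 0.0899 without control replicate 1, 0.109 without ovariectomized replicate 2 and 0.294 without ovariectomized replicate 3. BMP and TGF-beta genes had 0.109, 0.110 and 0.704 without control replicate 1, control replicate 3 and ovariectomized replicate 2, and osteocyte genes had 0.119, 0.120 and 0.925 without control replicate 2, control replicate 3 and ovariectomized replicate 2. Medians in log2(FPKM + 1) lay above 0 for BMP and TGF-beta genes without control replicate 3 (0.016) and ovariectomized replicate 2 (0.069), for osteocyte genes without ovariectomized replicate 2 (0.076), for erythroid genes without ovariectomized replicate 1 (0.017), and for cell cycle genes without control replicate 3 (0.00072) and ovariectomized replicate 1 (0.0039). Camera kept each of these on the lower side. On that scale the median of all genes was itself 0.038 with all 9 libraries. The other 20 of the 33 lists did not pass; osteoclast genes, for example, had 10 of 15 members lower and an adjusted p of 0.327.

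No gene passed the adjusted threshold in this comparison: edgeR's quasi-likelihood test called 0 of 13886 genes (smallest adjusted p = 0.669), with 701 at an unadjusted p under 0.05 where 694.3 are expected by chance, limma called 0, and DESeq2, added after seeing the data, called 59 (42 higher, 17 lower). At an unadjusted p under 0.05 and at least 2-fold, without control of false calls, 193 genes were higher and 49 lower, and without ovariectomized replicate 1 these counts were 222 and 108. The 2 groups did not overlap in 8.94% of genes, against 10% by chance. Without control replicate 1, edgeR called 4 genes, and without treated replicate 2, 2 genes. Among genes named by the rule for those that had not passed, Bnip3, a mitochondrial mediator of autophagy, had 18.4 ± 4.20 CPM in controls and 40.6 ± 4.27 CPM in ovariectomized rats (log2 fold change 1.14 ± 0.22 SE, edgeR adjusted p = 0.871; DESeq2 adjusted p = 0.00124). Aldh1a7, Ppp1r1a, Ubd and Hspa1b were other higher genes beside Lpl, at log2 fold changes of 3.57, 2.0, 1.19 and 1.02. The lower ones were B4galt6, a lactosylceramide synthase, at -1.06 ± 0.23, Krt76, Hist2h3c2, Snord100, Cemip, Col9a3, Il17b and Ccn5. Of these 14 genes, 9 passed in DESeq2. Hist2h3c2, Snord100 and Il17b rested on low levels, at 0.34, 0.28 and 0.45 CPM in ovariectomized rats. Hspa1b, Hist2h3c2 and other members of families with near-identical copies are uncertain where reads could be shared between copies, and so are overlapping genes.

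The genes most tied to bone turnover did not pass. Runx2, the master regulator of osteoblasts, was at -0.38 ± 0.17 (SE; edgeR adjusted p = 0.974). Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor that restrains osteoclasts, was at -0.95 ± 0.51. The osteoclast enzymes Acp5 and Ctsk were at -0.48 ± 0.43 and -0.25 ± 0.48, and the matrix genes Bglap and Col1a1 at -0.31 ± 0.73 and -0.38 ± 0.69. Signs turned without single libraries: Ctsk was at 0.12 without control replicate 3 and 0.02 without ovariectomized replicate 2, Bglap at 0.02 and 0.13 without control replicate 3 and ovariectomized replicate 1, and Col1a1 at 0.04 without ovariectomized replicate 1. Tnfsf11, the osteoclast differentiation factor RANKL, and the oestrogen receptor gene Esr1 fell below the filter, with 0 to 87 and 40 to 233 counts per library, and were not tested.

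Treated rats were compared with ovariectomized rats to ask what the herb changes. Genes switched on within minutes of cell stimulation or stress fell in treated rats, and this was the only list that passed camera at both the preset and the estimated correlation. All 22 measured members of the immediate early and heat shock list were lower, with a median log2 fold change of -0.26. Fos (chromosome 6, 109300433 to 109303299) went from 92.1 ± 22.0 CPM to 47.9 ± 3.53 CPM (SD, n = 3), a log2 fold change of -0.94 ± 0.15 (SE). Its relative Fosb was at -1.38 ± 0.25, the stress-induced factor Atf3 at -1.50 ± 0.28 and the heat shock chaperone Hspa1b (chromosome 20, 4877324 to 4879779) at -1.31 ± 0.22; Egr1 and Jun, chosen after their values were seen, were at -0.65 ± 0.14 and -0.69 ± 0.19. These 6 passed when adjusted over the list alone, and over all genes tested 0 of the list passed in edgeR and 5 in DESeq2 (Atf3, Fos, Egr1, Fosb and Hspa1b). The camera adjusted p was 4.48e-13, with adjusted p = 0.0226 with an estimated correlation, and fry gave an adjusted p of 0.0245. With the erythroid score as a covariate, added after seeing the data, the list did not pass at the estimated correlation (adjusted p = 0.0574), although its median difference in log2(FPKM + 1) went from -0.20 to -0.41 and the preset correlation gave an adjusted p of 9.16e-10. That median of -0.20 was -0.31 without ovariectomized replicate 3 and -0.30 without treated replicate 2.

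**Figure D2:**
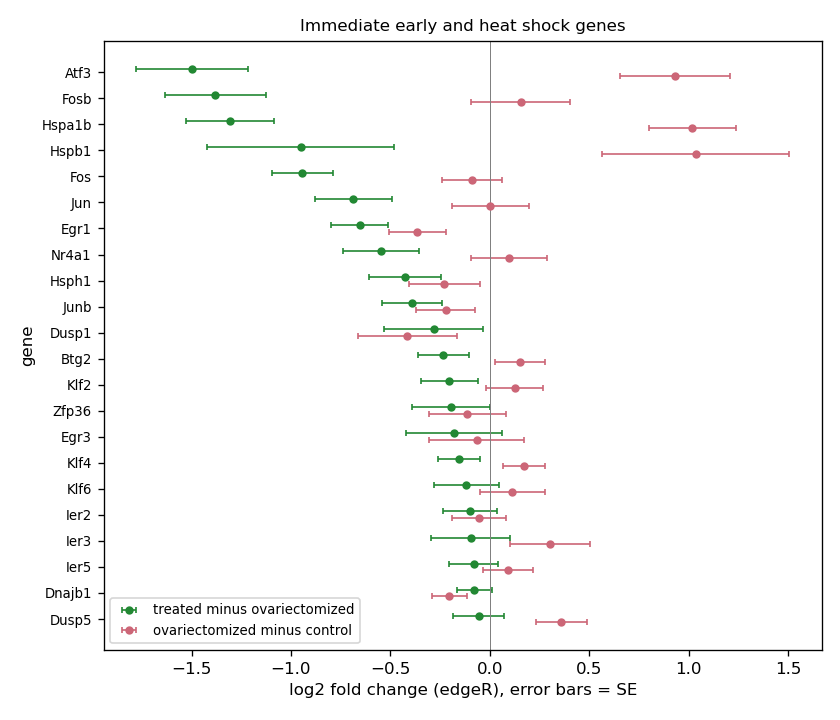
Log2 fold changes from edgeR (horizontal axis) of the 22 measured immediate early and heat shock genes (vertical axis), with SE as error bars, for treated minus ovariectomized and for ovariectomized minus control rats (n = 3 per group). All 22 estimates for treated minus ovariectomized rats lie below 0, from -1.50 for Atf3 to -0.06 for Dusp5, while 13 of the 22 for ovariectomized minus control rats lie above 0.

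Glucocorticoid-responsive and circadian genes were lower as well, 18 of 21 with a median of -0.29. Dbp, an output gene of the circadian clock, was at -0.86 ± 0.17, Nr1d2 at -0.49 ± 0.12, Nr1d1 at -1.31 ± 0.37 and Zbtb16 at -1.43 ± 0.36. In this list 5 genes passed when adjusted over the list alone and, over all genes tested, 0 in edgeR and 2 in DESeq2, Dbp and Zbtb16 (camera adjusted p = 5.20e-10; adjusted p = 0.150 with an estimated correlation). Fibroblast, periosteum and tendon genes were lower in 17 of 19 cases, with a median of -0.40. They included Thbs4 (-1.03 ± 0.26), Fmod (-1.13 ± 0.34), Dcn (-0.41 ± 0.13) and Col6a1 (-0.52 ± 0.16), and 6 passed when adjusted over the list alone against 0 in edgeR and 1 in DESeq2, Thbs4, over all genes tested (camera adjusted p = 7.76e-08; adjusted p = 0.441 with an estimated correlation). The fibroblast median in log2(FPKM + 1), -0.29, was -0.44 without ovariectomized replicate 2, -0.13 without ovariectomized replicate 3 and -0.51 without treated replicate 3. All 21 erythroid genes were lower (median -0.31), with the red cell transcription factors Gata1 at -0.27 ± 0.10 and Klf1 at -0.36 ± 0.13 and the membrane gene Epb42 at -0.46 ± 0.16. Their camera adjusted p was 1.55e-11, with adjusted p = 0.685 with an estimated correlation, and 0 members passed in edgeR when adjusted over the list alone, and 0 over all genes tested in edgeR or DESeq2.

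All 18 skeletal muscle genes were lower in treated than in ovariectomized rats, by a median of -1.24 (camera adjusted p = 2.36e-10; adjusted p = 0.685 with an estimated correlation). Pvalb, the calcium buffer of fast fibres, was at -1.28 ± 0.48 and Myl1 at -1.20 ± 0.51; 0 members passed in edgeR when adjusted over the list alone, and 0 over all genes tested in edgeR or DESeq2. The muscle median in log2(FPKM + 1), -0.94, was -1.50 without ovariectomized replicate 1 and -0.45 without ovariectomized replicate 3, where Pvalb and Myl1 were at -0.75 and -0.69. A further 5 lists passed camera, each with adjusted p = 0.907 with an estimated correlation, and each lost that call or turned without single libraries. Neutrophil granule genes were higher in 17 of 18 cases, with Mmp8 at 0.42 ± 0.16 (adjusted p 0.135 without ovariectomized replicate 3 and 0.422 without treated replicate 1). Megakaryocyte genes were higher in 16 of 19 (0.0810, 0.505 and 0.556 without ovariectomized replicates 1 and 3 and treated replicate 3). Interferon genes were lower in 28 of 29, and turned to a median of 0.36 with an adjusted p of 0.000107 without ovariectomized replicate 1. Oxidative phosphorylation genes were lower in 31 of 35 (0.760, 0.0623 and 0.0523 without ovariectomized replicate 3, treated replicate 1 and treated replicate 2). Mitochondrially encoded genes were lower in 12 of 13 (0.0531, 0.767, 0.168 and 0.412 without control replicate 3, ovariectomized replicate 3, treated replicate 1 and treated replicate 2). Without ovariectomized replicate 3 the medians of both in log2(FPKM + 1) lay above 0 (0.0034 and 0.0053), but camera kept both on the lower side. On that scale the median of all genes was itself 0.033 with all 9 libraries. The remaining 23 lists did not pass, among them the adipocyte list (11 of 19 lower, adjusted p = 0.346), the osteoblast list (15 of 17 lower, adjusted p = 0.0989) and the osteoclast list (8 of 15 higher, adjusted p = 0.718).

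For single genes, edgeR called 0 of 13886 (smallest adjusted p = 0.581), with 722 at an unadjusted p under 0.05 against 694.3 expected; limma called 0 and DESeq2 called 38 (10 higher, 28 lower). At an unadjusted p under 0.05 and at least 2-fold, 37 genes were higher and 66 lower, and this count of 103 became 231 (65 higher, 166 lower) without ovariectomized replicate 1. The groups did not overlap in 12.4% of genes, against 10% by chance. The higher gene with the smallest unadjusted p among those named by the rule was Rtn3, a membrane-shaping protein of the endoplasmic reticulum (chromosome 1, 222677365 to 222734241), with 75.8 ± 3.44 CPM in ovariectomized and 178 ± 11.0 CPM in treated rats (log2 fold change 1.23 ± 0.23 SE; edgeR adjusted p = 0.713, DESeq2 adjusted p = 0.000260). Its level in control replicate 1 was 79.7 CPM against 154 and 166 CPM in the other controls; edgeR called 1 gene, Rtn3, without control replicate 1. Leaving out control replicate 2 gave 2 calls and leaving out treated replicate 2 gave 1. B4galt6, Hist2h3c2, Sowaha, Tcp11, Gm26457 and Ankef1 were the other higher genes named by the rule, at 1.06, 1.38, 2.02, 1.0, 1.08 and 1.48, and did not pass in edgeR. For Gm26457 and Ankef1 the unadjusted edgeR p was 0.057 and 0.064. Gm26457, a snoRNA gene, rested on 0.060 CPM in ovariectomized and 0.129 CPM in treated rats. Besides Hspa1b, Fosb, Atf3, Zbtb16 and Thbs4, the lower ones were Lgals5, a galectin of red cell precursors (-1.15 ± 0.23), Ccdc146 (-1.80 ± 0.48) and a row for the ribosomal protein gene Rpl38 on chromosome 8 (-1.47 ± 0.36), which is uncertain because copies of that gene elsewhere are near-identical. Of these 15 genes, 9 passed in DESeq2 and 2 received no adjusted p there. Log2 fold changes were 0.02 ± 0.50 for Tnfrsf11b, 0.04 ± 0.43 for Acp5, -0.10 ± 0.48 for Ctsk, -0.07 ± 0.73 for Bglap, 0.07 ± 0.17 for Runx2 and -0.27 ± 0.69 for Col1a1, and none of the 6 passed. Each of the 6 turned sign without single libraries. Without ovariectomized replicate 1, 2 or 3 these were Ctsk (0.36), then Tnfrsf11b (-0.28), Acp5 (-0.18) and Runx2 (-0.05), then Acp5 (-0.06), Bglap (0.97) and Col1a1 (0.62). Without treated replicate 1, 2 or 3 they were Ctsk (0.18) and Bglap (0.06), then Tnfrsf11b (-0.59) and Acp5 (-0.39), then Bglap (0.32) and Col1a1 (0.08).

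Treated rats were also compared with controls, to see what still differed from normal femora. Adipocyte genes were higher in treated rats too, all 19 with a median log2 fold change of 0.996. Lpl was at 1.59 ± 0.34 (SE), Retn at 1.23 ± 0.32 and Pparg at 0.63 ± 0.20, and 2 members passed when adjusted over the list alone against 0 in edgeR and 2 in DESeq2, Lpl and Retn, over all genes tested (camera adjusted p = 1.90e-08; adjusted p = 0.472 with an estimated correlation). All 17 osteoblast genes were lower with a median of -0.67, including Ibsp, a sialoprotein of mineralized matrix, at -1.44 ± 0.51 and Bmp3 at -1.0 ± 0.34. All 10 osteocyte genes (median -0.33) and 15 of 16 cartilage genes (median -0.90; Col2a1 at -1.59 ± 0.66) were lower. These 3 lists passed camera (adjusted p = 6.21e-10, 0.000804 and 1.07e-07), each with adjusted p = 0.472 with an estimated correlation, and 0 of their members passed in edgeR when adjusted over the list alone or over all genes tested, where DESeq2 passed 1, the osteoblast gene Tnn. Medians in log2(FPKM + 1) were -0.56, -0.25 and -0.86, and without control replicate 3 they were -0.36 for osteoblast and -0.43 for cartilage genes. Leaving out treated replicate 2 gave -0.86 and -1.40 for these lists, and leaving out treated replicate 3 gave -0.56 for cartilage. Osteocyte genes were at -0.40 without control replicate 1, -0.15 without treated replicate 1 and -0.40 without treated replicate 3.

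All 21 erythroid genes were lower in treated rats than in controls, with a median of -0.48, and 12 passed when adjusted over the list alone against 0 in edgeR and 2 in DESeq2, Hemgn and Epb42, over all genes tested; Hemgn was at -0.63 ± 0.17 and Gata1 at -0.40 ± 0.10. The camera adjusted p was 3.80e-16, with adjusted p = 0.472 with an estimated correlation. Without control replicate 2, the library richest in haemoglobin, the erythroid median in log2(FPKM + 1) went from -0.38 to -0.21 and Hemgn was at -0.40. Immediate early and heat shock genes were lower in 17 of 22 cases (median -0.29), with Egr1 going from 122 ± 2.59 to 60.4 ± 6.81 CPM (-1.02 ± 0.14) and Fos and Junb at -1.03 ± 0.15 and -0.61 ± 0.15. Of that list 7 passed when adjusted over the list alone and, over all genes tested, 0 in edgeR and 5 in DESeq2, Hsph1, Fos, Egr1, Junb and Fosb (camera adjusted p = 1.07e-07; adjusted p = 0.111 with an estimated correlation). Fibroblast genes (14 of 19 lower, median -0.46; Postn at -1.69 ± 0.43, 5 adjusted over the list alone and, over all genes tested, 0 in edgeR and 4 in DESeq2) and glucocorticoid and circadian genes (17 of 21 lower, median -0.30; Fkbp5 at -0.21 ± 0.06) had camera adjusted p values of 1.27e-05 and 3.37e-05, each with adjusted p = 0.472 with an estimated correlation. Leaving out control replicate 3 took the fibroblast median in log2(FPKM + 1) from -0.22 to -0.11. A further 4 lists lost their calls without single libraries. They were neutrophil genes (18 of 18 higher; adjusted p 0.105 without control replicate 3), cell cycle genes (29 of 29 lower; 0.821 without control replicate 2), oxidative phosphorylation (24 of 35 higher; 0.215 without control replicate 1, 0.189 without treated replicate 3) and Wnt signalling (15 of 21 lower; 0.110, 0.0729 and 0.102 without control replicates 1 and 3 and treated replicate 1). Medians in log2(FPKM + 1) lay above 0 for cell cycle genes without control replicate 2 (0.046) and for Wnt genes without control replicate 3 (0.086). Camera kept both of these on the lower side, and the median of all genes on that scale was itself 0.078 with all 9 libraries. With an estimated correlation these 4 had adjusted p = 0.866, adjusted p = 0.971, adjusted p = 0.971 and adjusted p = 0.652. The skeletal muscle list did not pass (18 of 18 higher, median 0.61, adjusted p = 0.0547).

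In this comparison edgeR again called 0 of 13886 genes (smallest adjusted p = 0.340), with 1223 at an unadjusted p under 0.05 against 694.3 expected; limma called 0 and DESeq2 called 153 (65 higher, 88 lower). At an unadjusted p under 0.05 and at least 2-fold, 83 genes were higher and 75 lower, and this count of 158 became 285 (121 higher, 164 lower) without treated replicate 2; without control replicate 1, 130 were higher and 93 lower. Rescaling to TPM, fitted with limma, moved the median of all genes to 0.17 on the log2 scale and gave 111 higher and 28 lower genes. Limma on log2(FPKM + 1) gave a median of 0.078, with 79 higher and 33 lower. Limma after quantile normalization gave a median of -0.00092, with 56 higher and 41 lower. With limma the balance of directions thus moved with the scaling, and the part of the tool was not separated. The groups did not overlap in 13.1% of genes, against 10% by chance. Leaving out control replicate 1, control replicate 2, ovariectomized replicate 1 or treated replicate 2 gave 3, 1, 2 and 3 calls in edgeR. Genes named by the rule were Ubd, a ubiquitin-like modifier, at 1.84 ± 0.25, Tmcc3 (1.48 ± 0.27), Pirb (2.23 ± 0.42) and Kcnn3 (1.59 ± 0.32) on the higher side and Egr1, Fos, Lgals5 (-1.51 ± 0.24), Slc29a2 (-1.14 ± 0.21) and Fosb (-1.23 ± 0.25) on the lower side; all 9 passed in DESeq2 and 0 in edgeR. Pirb belongs to a receptor family with similar copies. The bone turnover genes did not pass, with Tnfrsf11b at -0.92 ± 0.51, Acp5 at -0.43 ± 0.43, Ctsk at -0.35 ± 0.48, Bglap at -0.38 ± 0.73, Runx2 at -0.32 ± 0.17 and Col1a1 at -0.65 ± 0.69. Ctsk was at 0.02 without control replicate 3 and Bglap at 0.01 without treated replicate 3, and the estimates of Tnfrsf11b and Col1a1 were further below 0 without treated replicate 2.

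Whether treatment moved expression back towards controls was examined across genes. The ovariectomy difference and the treatment difference had a Pearson r of -0.51 over 13886 genes, which are not independent replicates. Because both differences contain the same ovariectomized libraries, unchanged groups give a negative r as well: 1000 simulated draws had a mean of -0.50, with 95% of draws between -0.64 and -0.34. The covariance was -0.118 against a simulated mean of -0.0849, with 95% of draws between -0.129 and -0.0511. Its size changed with the estimator, to -0.0407 with limma and -0.93 in edgeR with no filter. Rows with very large estimates weigh on it, such as a placeholder symbol at -12.0 for ovariectomy and 12.4 for treatment. The distance of the covariance from the simulated mean therefore cannot decide whether there was a reversal. The 3 shared libraries are too few to be divided between the comparisons, so what these libraries alone contribute was not removed. In edgeR 0 genes were called in both comparisons. At the looser threshold 25 genes were higher after ovariectomy and lower after treatment, and 11 the reverse; the shared libraries produce such overlap without any change, and no expectation that allows for them was computed. Named by the rule in both comparisons, Hspa1b (1.02 and -1.31), B4galt6 (-1.06 and 1.06) and Hist2h3c2 (-1.33 and 1.38) had opposite signs and differed from controls after treatment by -0.29, -0.00 and 0.05. Many of the 25 were muscle genes, among them Myl1, Pvalb, Casq1, Eno3, Tmod4, Myoz1, Lmod3, Klhl40 and Trim54, chosen after their values were seen. That part of the overlap follows the muscle pattern, which may reflect dissection, the operation or both.

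Of 3303 gene ontology and KEGG terms tested, camera called 140 for ovariectomized against control rats (98 higher, 42 lower), 18 for treated against ovariectomized rats (0 higher, 18 lower) and 69 for treated rats against controls (23 higher, 46 lower); 0 held with an estimated correlation and fry called 0. The 140 became 87 without control replicate 3 and the 69 became 105 without control replicate 1. The 18 became 70 and 5 without ovariectomized replicates 1 and 3, and 6 and 38 without treated replicates 2 and 3. After ovariectomy, muscle contraction (29 of 35 genes higher, median 1.61) and the citrate cycle (28 of 28 higher, median 0.12) stood out above, and the nucleosome (57 of 74 lower, median -0.36) below. In treated against ovariectomized rats all 12 genes of porphyrin biosynthesis, the pathway to haem, were lower (median -0.29), as were 66 of 87 genes of the collagen-containing extracellular matrix (-0.21) and 13 of 14 of protein refolding (-0.20). Against controls, treated rats were lower in collagen fibril organization (36 of 44, -0.53) and higher in fatty acid beta-oxidation (31 of 34, 0.16) and the PPAR signalling pathway (37 of 48, 0.24). All of these named terms had adjusted p = 0.999, adjusted p = 0.9997 and adjusted p = 0.997 with an estimated correlation in the order of the comparisons.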

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

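The alternatives with limma, DESeq2, edgeR log2 CPM and the skeletal muscle score were chosen after seeing the data, as were the splits with DESeq2. In the order ovariectomized against control, treated against ovariectomized and treated against control, the counts of genes past the adjusted threshold were 0, 0 and 0 in edgeR, 2, 1 and 1 with only the 2 groups compared, and 59, 38 and 153 with DESeq2. At the looser threshold the counts of 242, 103 and 158 were 529, 295 and 383 with no filter and 115, 46 and 71 at a mean FPKM of at least 5, which tests more or fewer genes. With limma, treated against ovariectomized rats gave 58 rescaled to TPM, 52 with quantile normalization and 48 on log2(FPKM + 1). EdgeR with median-of-ratios scaling gave 103. Treated against control rats gave 97 with quantile normalization and 112 on log2(FPKM + 1), both with limma. Limma with a pseudocount of 0.1 gave 75 and 177 in turn. The counts moved with the pseudocount, and the tool's part was not separated. The counts of lists past the threshold, 13, 10 and 12, were 0, 1 and 0 with an estimated correlation and 0, 1 and 1 with fry. The list that fry called for treated against control rats was apoptosis and autophagy, which camera did not call. Its median was 0.12 in log2(FPKM + 1), where the median of all genes was itself 0.078. In edgeR its median was 0.054, with 15 of 25 members higher. With the muscle score as a covariate 6 lists passed for treated against ovariectomized rats, of which the adipocyte list was not among the 10. Of 140, 18 and 69 terms, 0, 0 and 0 were left with an estimated correlation and 0, 0 and 0 with fry. For treated against ovariectomized rats terms numbered 8 with no filter, 33 when rescaled to TPM and 28 with the muscle score as a covariate, and for treated against control rats 156 with no filter; the cause was not tested. The correlation of the ovariectomy and treatment differences, -0.51, was -0.79 with the muscle score as a covariate, for which no value for unchanged groups was simulated, so the shift says nothing about reversal. Rescaling to TPM, fitted with limma, moved the median of all genes to 0.10 for ovariectomized and 0.17 for treated rats against controls. Limma on log2(FPKM + 1) gave 0.038 and 0.078. The robust variance model has no counterpart in camera and was run for genes only.

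With each library left out in turn, genes past the threshold ran from 0 to 4, 0 to 2 and 0 to 3, the looser counts from 183 to 330, 89 to 231 and 126 to 285, lists from 10 to 16, 7 to 16 and 11 to 16, and terms from 87 to 171, 5 to 70 and 52 to 105. The correlation of the differences ran from -0.70 to -0.37. The median of the interferon list ran from -0.11 to 0.88 for ovariectomized against control rats and from -0.62 to 0.36 for treated against ovariectomized rats, both turning without ovariectomized replicate 1, the library with the high interferon values. Where a group kept 2 libraries, its spread came from the pooled fit. With the replicate number as a block, the counts were 0, 0 and 0 genes, 220, 72 and 161 genes at the looser threshold, 13, 13 and 15 lists and 133, 39 and 79 terms. Libraries with the same number correlated by -0.13 to 0.18 after removing group means, over 0.1 in 1 of 9 pairs, and 3 of 9 libraries correlated best with their own number. The block thus has no support as a pairing. At 54992823 to 66531156 counts per library, the spread between libraries exceeded sampling noise in every pair, with a lowest chi-square per degree of freedom of 80.02.

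Each comparison of 6 libraries allows 10 splits into 3 and 3, so no share can fall under 0.05 and the splits neither exclude chance nor show it. For ovariectomized against control rats, edgeR called 0 genes in the real split and up to 4 in another (10 of 10 splits as large), DESeq2 59 and up to 267 (3), the looser threshold 242 and up to 278 (2), lists 13 and up to 20 (7) and terms 140 and up to 299 (4). For treated against ovariectomized rats, the values were 0 and 1 genes (10), 38 and 61 with DESeq2 (3), 103 and 216 at the looser threshold (4), 10 and 19 lists (10), 1 and 0 lists with an estimated correlation (1) and 18 and 126 terms (8). For treated against control rats, they were 0 and 4 genes (10), 153 and 510 with DESeq2 (2), 158 and 171 at the looser threshold (2), 12 and 15 lists (6) and 69 and 230 terms (2). With an estimated correlation, the real split of ovariectomized against control rats called 0 lists. Setting control replicate 2 and ovariectomized replicates 1 and 2 against the rest called 1 list, and the remaining splits called 0. Every split of treated against control rats called 0 lists with an estimated correlation. The split with 267 genes set control replicate 2 and ovariectomized replicates 2 and 3 against the other 3 libraries, and the split with 510 set control replicates 2 and 3 and treated replicate 2 against the others. Splits that called several times the real count point to a structure of the samples, whose origin was not tested.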

Other observations

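The tests of the muscle, immediate early and adipocyte patterns below were all chosen after the results were seen. Among clock genes, the outputs that peak together were lower in treated than in ovariectomized femora, 7 of 7 measured, with a median log2 difference of -0.49. The SE over the 7 genes was 0.14. These genes share their libraries, so this SE does not measure the spread between libraries. Dbp was at 20.6 to 33.1 CPM in ovariectomized and 13.9 to 16.4 CPM in treated libraries, and Nr1d1 at 14.5 to 26.6 and 6.61 to 10.4 CPM. Per1 did not part in the same way, with 29.4 and 33.9 CPM in treated replicates 2 and 1 but 86.4 CPM in treated replicate 3. Pirb, an inhibitory receptor of myeloid cells, was at 14.1 to 23.4 CPM in controls and 78.8 to 103 CPM in treated libraries, while the ovariectomized libraries held 85.1, 82.4 and 25.8 CPM.

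Skeletal muscle genes were higher in ovariectomized than in control femora. Within groups the members deviated together, with a median pairwise correlation of 0.938, as muscle tissue carried along with the bone in differing amounts requires. High values are not particular to carried tissue, since the interferon, erythroid and cell cycle lists had 0.846, 0.820 and 0.801 and the immediate early list 0.0658. The scores ran from -2.17 to -0.28 in controls and from -0.18 to 2.11 in ovariectomized rats. An effect of ovariectomy on muscle transcripts stays open, since 3 libraries against 3 cannot go under the exact permutation p of 0.1 that was found. The direction of the muscle list may therefore reflect dissection, the operation or both.

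Immediate early and heat shock genes were lower in treated than in ovariectomized femora. Differing amounts of muscle RNA do not account for the whole pattern: with the muscle score as a covariate the median of log2(FPKM + 1) differences was -0.28, against -0.20 without, and the adjusted p with an estimated correlation was 0.00633. With the erythroid score as a covariate the median was -0.41 and the preset correlation still gave an adjusted p of 9.16e-10, but with an estimated correlation it was 0.0574, so that call ended while the median grew. Another time of day at collection could lower clock outputs and immediate early genes together, and it stays open. The 4 measured clock genes of the opposite phase had a median of 0.054, with an SE of 0.080 over the 4 genes. That SE does not measure the spread between libraries, so these values cannot decide the question. The treatment stays open as well, with an exact permutation p of 0.1, and so does handling between death and freezing, which was not tested.

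Adipocyte genes were higher in ovariectomized and in treated than in control femora. With the muscle score as a covariate the medians of log2(FPKM + 1) differences were 1.36 and 1.17, against 1.14 and 1.07 without. The medians thus did not shrink as fat in proportion to muscle RNA would require. The covariate follows muscle transcripts only, so it cannot decide on attached fat whose amount varies apart from muscle. The low values of control replicate 3, whose score was -1.63 against -0.28 in both other controls, made up part of the difference. Without that library the medians were 0.70 and 0.75, with only the other controls left to compare. The list stayed past the camera threshold at the preset correlation. That call decides nothing, since up to 20 lists passed it in other splits of ovariectomized and control libraries. With an estimated correlation the list did not pass (adjusted p = 0.745 and adjusted p = 0.472, or 0.633 and 0.561 with the muscle score). More marrow fat after loss of the ovaries is a possible explanation (exact permutation p of 0.1), and fat from outside the marrow was not tested.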
